A study of Homo sapiens with 4 samples.

How the data were processed

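RNA from SK-LMS-1, a human leiomyosarcoma cell line, was sequenced in 4 libraries. Per the labels, 2 libraries came from untreated cells and 2 from cells exposed to 2-D08 at 50 µM for 48 h. 2-D08 is a flavone that inhibits the attachment of the small protein modifier SUMO to its substrates. The labels call the reference cells untreated and do not state a vehicle. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a Roche kit. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

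Per the submitters' processing notes, cutadapt 3.4, STAR 2.7.8a, DESeq2 and the GRCh38 build were used. The counting tool, its handling of strand and of reads shared between genes, and the annotation release are not given in the sources used here. The authors deposited 3 tables, each with a column per library and no column without a mapped sample. The first holds whole-number read counts per gene, not normalised, for 19381 genes. The second holds deposited TPM values, read abundance scaled for transcript length and depth, in which the listed genes sum to 716934 to 761770 per library. The third is named by the authors as normalised counts, but its deposited values run from 6.35 to 18.3 on a log2 scale with a shared lowest value, so it was read as log2-like transformed values and used only for an alternative. Symbols were matched to GENCODE release 29 for position, transcript length and GC content, and 19354 of them matched. The release used for counting can differ.

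Total counts were 29586475 and 16628710 in the untreated libraries and 14796702 and 31300635 in the treated ones. In untreated replicate 1 and treated replicate 2 most counts of the genes named below were even numbers. Reads there may have been counted more than once, which was not tested. Tests, bounds and intervals take each count as a separate read. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0. Genes were filtered with filterByExpr (minimum count 10), which left 12906 genes, and scaled with TMM factors. Levels are given as CPM, counts scaled to library size, after TMM scaling, unless stated otherwise. Treated and untreated libraries were compared with edgeR's quasi-likelihood test (robust, two-sided) with Benjamini-Hochberg adjustment, and genes with adjusted p under 0.05 were called changed. Standard errors of log2 fold changes were derived from the test's F statistic. A gene with no count in a group was given only a lower bound of its fold, against a floor of 3 counts over the group, which covers counting error only.

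Before the data were examined, 27 gene lists, the tests, most alternatives and the rule for named genes were fixed. That rule named 6 genes of the SUMO pathway. It also named the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM, non-overlapping groups and an ordinary symbol. It further named up to 4 members with the smallest p from each list among those with a mean of at least 1 CPM. Some genes that the rule names are not reported here. Lists with at least 3 tested members were compared with all other genes by camera (two-sided) on voom values with a preset correlation of 0.01, adjusted over 26 lists. Camera was repeated with an estimated correlation, which has 2 residual degrees of freedom here, and fry was run as a self-contained test. Mitochondrially encoded genes are not analysed here.

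The count and list scripts were tested on simulated data made from the means and library sizes of these libraries, with 200 genes changed among 12906. For the comparison of treated with untreated libraries, 73.1% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold were recovered. Of 181 calls, 4.4% were false. All simulated genes in both groups shared a single dispersion (0.00727). In the real data far more genes were called and the treated pair differed more, so these rates may not carry over.

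The other settings tried were RLE size factors, library size only, no low-count filter, a mean of at least 5 CPM, DESeq2, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, and leaving out each library in turn. A fit on the transformed values, counts thinned to the smallest library, removal of a trend on transcript length and GC content, and 10 further gene lists were added after the data had been seen.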

Results

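Gene expression was measured by RNA sequencing in SK-LMS-1 leiomyosarcoma cells. They were left untreated (2 libraries) or exposed for 48 h to 50 µM 2-D08, an inhibitor of SUMO attachment (2 libraries). Library totals ran from 14796702 to 31300635 counts, and the lower total lay in a different replicate number in each group. The libraries with the higher totals, untreated replicate 1 and treated replicate 2, held mostly even counts among named genes. They had reads on 14482 and 15603 genes, against 14659 and 15816 in the other library of their group. Their totals may therefore overstate depth, and the cause was not tested. Across genes, log2 CPM correlated with Pearson's r of 0.992 between the untreated libraries and 0.99 between the treated ones, against 0.965 to 0.972 between groups; genes are not independent replicates. Against sampling noise, the chi-square per degree of freedom was 4.64 for the untreated pair and 13.9 for the treated pair. Reads counted more than once would raise both values. The first principal component held 73.4% of the variance and separated the groups. The 5099 genes with a mean under 0.1 CPM together took 56.6 and 57.6 CPM in the untreated libraries and 172 and 157 CPM in the treated ones. These sums were scaled to total counts without TMM factors.

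The comparison of treated with untreated cells asked which transcripts changed with the compound. Of 12906 genes tested, 4376 (33.9%) changed, 2201 higher and 2175 lower in treated cells. Of these, 815 changed at least 2-fold, 421 higher and 394 lower. HSPA6, a stress-inducible HSP70 chaperone gene on chromosome 1 (161524540 to 161526910, GRCh38), had 0 counts in both untreated libraries. The treated ones had 205 and 360 counts (edgeR adjusted p = 2.81e-08). That is at least 189-fold higher if each count is a separate read, which is uncertain for treated replicate 2. HSPA6 has a near-identical pseudogene copy, so its own share of these reads is uncertain. ID2, an inhibitor of basic helix-loop-helix transcription factors, went from 3.04 ± 0.581 to 46.2 ± 1.41 CPM (SD, n = 2 per group), a log2 fold change of 3.96 ± 0.16 (SE; edgeR adjusted p = 1.76e-09). Other large rises were those of ANGPTL4 (3.41), STC1 (2.69) and ESM1 (2.25 on the log2 scale), which encode secreted proteins. SCD, the stearoyl-CoA desaturase (chromosome 10, 100347124 to 100364834), went from 1102 ± 18.3 to 152 ± 2.41 CPM, a log2 fold change of -2.85 ± 0.09 (edgeR adjusted p = 2.69e-10). SREBF1, which encodes the lipogenic factor SREBP1, went from 49.1 ± 4.14 to 7.65 ± 0.365 CPM (log2 fold change -2.69 ± 0.14, edgeR adjusted p = 1.19e-08). Other large falls were those of ADCYAP1 (-3.06), GDF5 (-2.85), SLC2A12 (-2.77), L1CAM (-2.63), IGFBP5 (-2.61), GRIN2A (-2.58), CRISPLD2 (-2.46) and LIPG (-2.43). The count of changed genes was 1866 without untreated replicate 1, 2695 without untreated replicate 2, and 1695 and 1712 with limma on log2(TPM + 1) and log2(TPM + 0.1). The count changed at least 2-fold was 348 with a mean of at least 5 CPM required, 320 and 517 on the TPM scales, and 145 on the deposited transformed values, a fit added after the data had been seen.

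**Figure D1:**
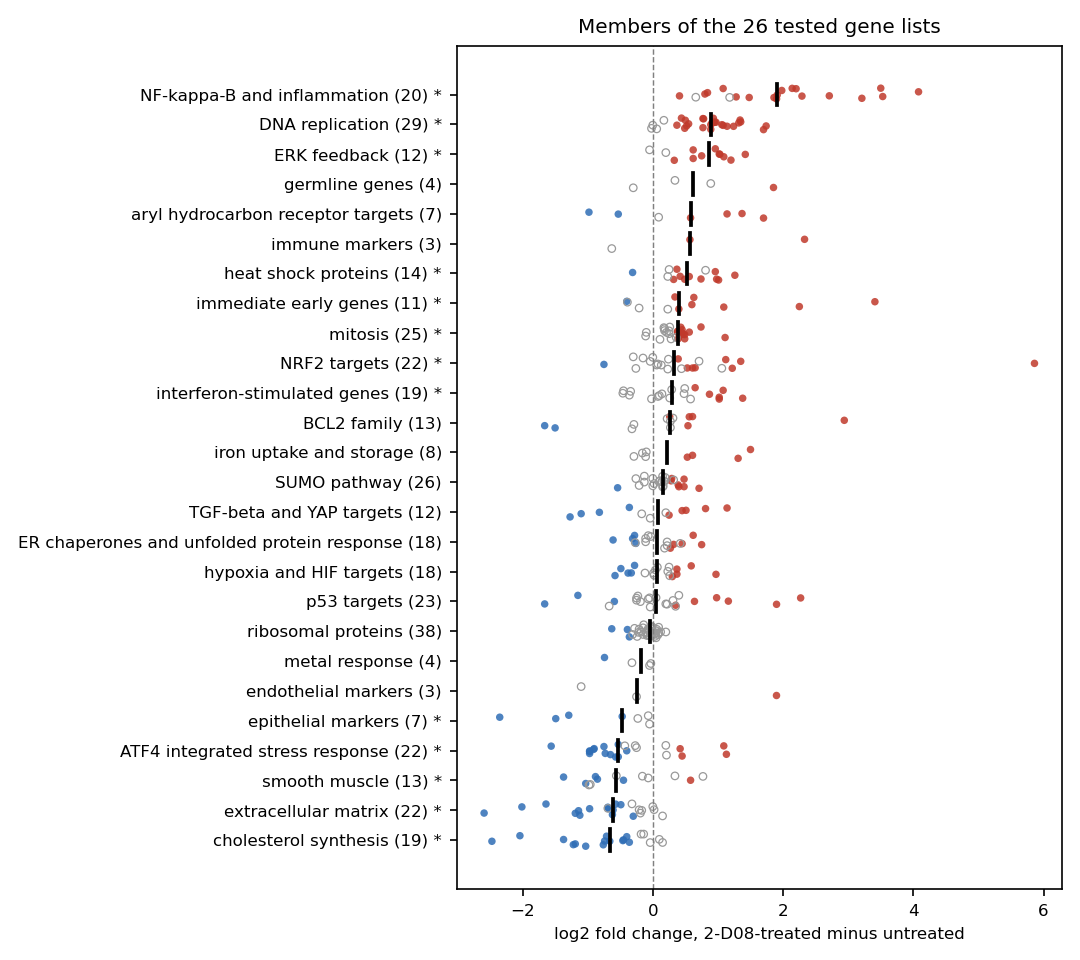
Each point is a tested member of 1 of 26 gene lists, placed by its log2 fold change (treated minus untreated), filled red (higher) or blue (lower) where edgeR's adjusted p was under 0.05 and open otherwise; black bars are list medians, numbers in brackets count tested members, and stars mark lists past camera's threshold with the preset correlation. Medians run from -0.66 (cholesterol synthesis) to 1.90 (NF-kappa-B and inflammation), and the points for AKR1C1, TNF and CSF2 are fitted values resting on 2, 2 and 3 untreated counts.

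With camera's preset correlation 13 of 26 lists passed the threshold, 8 upward and 5 downward, and with an estimated correlation 0 of 26 did. Both adjusted p-values are given for each of the 13 lists.

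Transcripts of NF-kappa-B and inflammation genes rose: 18 of 20 tested members were higher and 0 lower (20 higher when adjusted over the list alone), with a median log2 fold change of 1.90. CXCL8, a neutrophil chemokine (chromosome 4, 73740506 to 73743716), went from 5.69 ± 0.605 to 63.5 ± 0.52 CPM (SD, n = 2 per group; log2 fold change 3.50 ± 0.13, edgeR adjusted p = 1.14e-09). BIRC3, an inhibitor of apoptosis and an NF-kappa-B target (chromosome 11, 102317450 to 102339403), went from 25.9 ± 1.73 to 239 ± 20.8 CPM (3.21 ± 0.11, edgeR adjusted p = 2.69e-10). The collagenase gene MMP1 went from 198 ± 3.27 to 870.2 ± 13.7 CPM and MMP3 from 23.2 ± 1.84 to 86.1 ± 0.126 CPM. CXCL1 (2.71) shares sequence with CXCL2 and CXCL3, so its value is uncertain where reads could be split. Camera gave an adjusted p of 2.71e-14, and the adjusted p was 0.194 with an estimated correlation. Of 3 tested immune markers, LCP1 rose from 1 to 5.18 CPM and CD68 from 62.9 to 93 CPM, and the list did not pass (camera adjusted p = 0.123). LCP1 lost its call on both TPM scales (adjusted p of 0.0725 and 0.101).

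DNA replication genes also rose, 25 higher and 0 lower of 29 (25 adjusted over the list alone), with a median of 0.89 (camera adjusted p = 8.65e-16, and adjusted p = 0.194 with an estimated correlation). CDC6, which loads the replicative helicase, went from 32.4 ± 2.91 to 109 ± 0.661 CPM (SD, n = 2 per group; 1.74 ± 0.10, edgeR adjusted p = 6.3e-08). RRM2, a ribonucleotide reductase subunit, went from 440.3 ± 24.2 to 1039 ± 4.72 CPM. CCNE2 rose by 1.70 and CHAF1A by 1.14 on the log2 scale. Of 25 mitosis genes 13 were higher and 0 lower (15 adjusted over the list alone), with a median of 0.38. CDK1 (1.11) and BIRC5 (0.56) were among them. The mitosis list gave a camera adjusted p of 2.93e-06, an adjusted p of 0.468 with an estimated correlation and of 0.0725 with fry.

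Genes of ERK feedback rose in 10 of 12 cases with 0 lower (11 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 9.37e-08, and adjusted p = 0.237 with an estimated correlation). They included CCND1, which encodes cyclin D1 (1.20 ± 0.09 SE), SPRY4 (1.42 ± 0.13) and the ERK phosphatase gene DUSP6 (1.09). Among immediate early genes 7 were higher and 1 lower of 11 (8 and 2 adjusted over the list alone), with a median of 0.40. FOS rose by 3.41, FOSB by 2.25, ATF3 by 1.09 and JUN by 0.60, whereas EGR1 was the 1 gene called lower (-0.40). The list gave a camera adjusted p of 0.00833, an adjusted p of 0.52 with an estimated correlation and of 0.0693 with fry.

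Heat shock protein genes were higher in 10 and lower in 1 of 14 cases (12 and 1 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 1.77e-06, and adjusted p = 0.213 with an estimated correlation). The cochaperone gene DNAJA1 went from 211 ± 1.86 to 416 ± 37.6 CPM (SD, n = 2 per group) and HSPH1 rose by 0.96. HSPA1B (1.26) and HSPA1A (1.01) are near-identical copies, so their separate values are uncertain. Of 22 NRF2 targets, antioxidant genes, 8 were higher and 1 lower (11 and 3 adjusted over the list alone), with a median of 0.32. NQO1 rose by 1.22 ± 0.11 and GCLM by 1.12 ± 0.10 (SE), whereas SLC7A11 was the 1 target called lower (-0.75). AKR1C1, uncertain because of close paralogs, had 0 and 2 counts in the untreated libraries and 40 and 93 in the treated ones. The NRF2 list gave a camera adjusted p of 0.00578, and the adjusted p was 0.332 with an estimated correlation. Interferon-stimulated genes were higher in 6 and lower in 0 of 19 cases (8 adjusted over the list alone), with a median of 0.29. OAS3 (1.08), IFI44 (1.02) and IFI44L (1.38) rose. That list gave a camera adjusted p of 0.0261, and the adjusted p was 0.336 with an estimated correlation.

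Cholesterol synthesis genes fell: 0 were higher and 14 lower of 19 (14 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 1.6e-07, and adjusted p = 0.213 with an estimated correlation). INSIG1, which retains SREBP in the endoplasmic reticulum (chromosome 7, 155297776 to 155310235), went from 303 ± 10.5 to 73.6 ± 5.63 CPM (SD, n = 2 per group; -2.04 ± 0.10, edgeR adjusted p = 6.94e-09). LSS (-1.37) and SREBF2 (-1.19) also fell. In the ATF4 integrated stress response list 4 genes were higher and 13 lower of 22 (5 and 14 adjusted over the list alone), with a median of -0.53. ASNS, the asparagine synthetase, went from 497 ± 6.99 to 254 ± 3.62 CPM, and PSAT1 (-0.97) and DDIT4 (-1.56) fell, whereas PPP1R15A rose by 1.13. The ATF4 list gave a camera adjusted p of 0.000278, an adjusted p of 0.511 with an estimated correlation and of 0.066 with fry.

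Extracellular matrix genes fell in 14 of 22 cases with 0 higher (16 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.4e-08, and adjusted p = 0.336 with an estimated correlation). COL1A2, a type I collagen chain (chromosome 7, 94394561 to 94431232), went from 575 ± 31.2 to 143 ± 8.33 CPM (SD, n = 2 per group), 4.04-fold lower (edgeR adjusted p = 6.35e-09). COL1A1 (-1.19), COL11A1 (-1.64) and the fibronectin gene FN1 (-1.12) fell as well. Genes of the smooth muscle list, chosen for the lineage of this tumour type, were higher in 1 and lower in 5 of 13 cases (1 and 5 adjusted over the list alone). Their median was -0.56. In the untreated libraries DES and MYOCD had 0 counts and MYH11 lay at 0.472 and 0.726 CPM. The list therefore says little about loss of a smooth muscle programme. MYLK, the myosin light chain kinase, went from 329.5 ± 6.23 to 128 ± 8.5 CPM, and MYL9 (-0.88) and TAGLN (-0.85) fell, whereas SMTN rose by 0.58. That list gave a camera adjusted p of 0.0253, and the adjusted p was 0.336 with an estimated correlation. Epithelial markers moved with both lists, with 0 higher and 4 lower of 7 (4 adjusted over the list alone) and a median of -0.47. KRT19 fell by 1.49 and KRT7 by 1.29. The epithelial list gave a camera adjusted p of 0.0134, an adjusted p of 0.468 with an estimated correlation and of 0.0719 with fry.

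**Figure D2:**
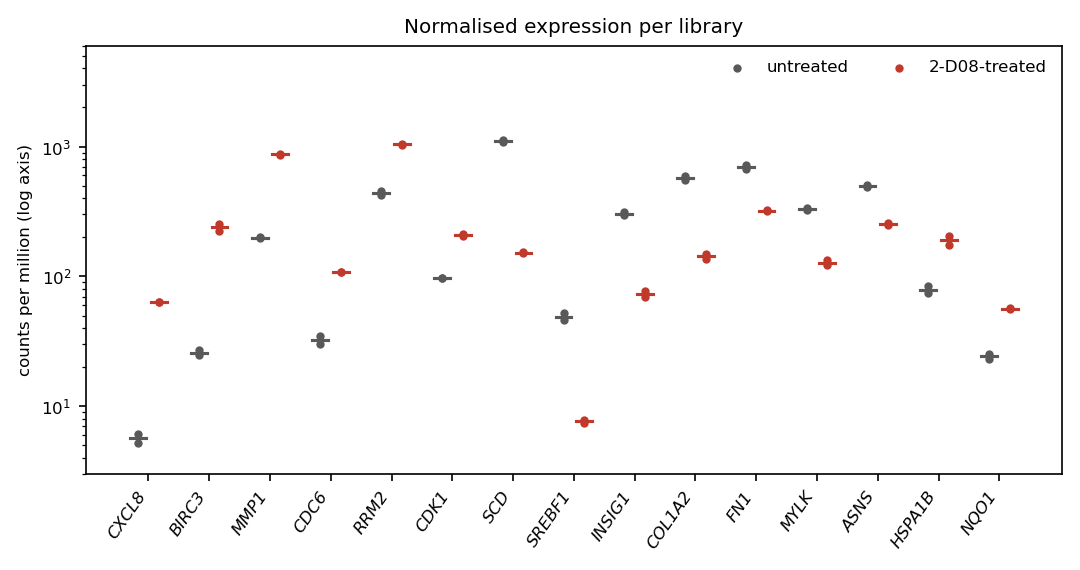
Points are CPM of single libraries on a log axis for 15 genes, with untreated libraries in grey and treated ones in red, and short bars mark the mean of 2 libraries. SCD lies at 1102 CPM in untreated and 152 CPM in treated cells, and CXCL8 at 5.69 and 63.5 CPM.

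Of genes of the SUMO pathway itself, the machinery that 2-D08 acts on, 7 of 26 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0552). SAE1 (0.00), SUMO2 (0.10) and SUMO3 (0.02) did not pass the test, and the fitted sign of SAE1 and SUMO3 differed between settings. UBA2 rose by 0.28 (edgeR adjusted p = 0.029), a call lost without untreated replicate 1 (adjusted p = 0.374), without untreated replicate 2 (0.21) and on both TPM scales. RNF4, a SUMO-targeted ubiquitin ligase (0.48), and SENP1, a SUMO protease (0.48), lost their calls without untreated replicate 1 (adjusted p of 0.0648 and 0.12), and SENP1 also on both TPM scales (0.0686 and 0.0656). SENP7, another SUMO protease gene, fell by 0.54 and lost its call without untreated replicate 2 (adjusted p = 0.0893).

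Other lists did not pass camera's threshold. Aryl hydrocarbon receptor targets had 4 higher and 2 lower of 7 (4 and 2 adjusted over the list alone, camera adjusted p = 0.231). SERPINB2 rose by 1.14, and CYP1A1 by 1.70 at low and uneven levels (3.32 and 1.04 CPM in the treated libraries). The receptor's repressor gene AHRR fell (-0.98), a call lost with limma on log2(TPM + 0.1) (adjusted p = 0.06). The p53 targets had 6 higher and 3 lower of 23 (7 and 3 adjusted over the list alone; 0.374), with CDKN1A at 15.9 ± 1.53 and 60.1 ± 11.8 CPM and TP53INP1 lower (-1.15). Both lists passed camera without treated replicate 2 (adjusted p of 0.017 and 0.0203). Iron uptake and storage genes had 4 higher and 0 lower of 8 (4 adjusted over the list alone; camera adjusted p = 0.147), and the transferrin receptor gene TFRC went from 194 ± 2.72 to 548 ± 2.67 CPM. This list passed with fry (adjusted p = 0.0113) and in each of the 4 fits that left out a library (0.00137 to 0.0484). The BCL2 family had 5 higher and 2 lower of 13 (7 and 2 adjusted over the list alone, camera adjusted p = 0.179). BCL2A1 rose by 2.94 at low levels (0.576 to 4.44 CPM). The pro-apoptotic genes BMF (-1.50) and BBC3 (-1.66, from 3.04 to 0.987 CPM) were lower. The pro-apoptotic genes PMAIP1 (0.54, and 0.46 without untreated replicate 1) and BAK1 (0.56) were higher. Endoplasmic reticulum chaperones had 5 higher and 4 lower of 18 (5 and 5 adjusted over the list alone; 0.569), among them MANF (0.75) and HERPUD1 (-0.61). Hypoxia and HIF targets had 5 higher and 5 lower of 18 (5 and 5 adjusted over the list alone; 0.529), among them ADM (0.97) and BNIP3L (-0.49). TGF-beta and YAP targets had 5 higher and 4 lower of 12 (5 and 4 adjusted over the list alone; 0.948), with AXL lower (-0.82) and ANKRD1 higher (0.81). Their median of 0.08 and mean of -0.03 differed in sign. Ribosomal protein genes had 0 higher and 3 lower of 38 (0 and 1 adjusted over the list alone; 0.19), the metal response list 0 and 1 of 4 (0 and 1; 0.209), germline genes 1 and 0 of 4 (0 and 0; 0.448) and endothelial markers 1 and 0 of 3 (1 and 0; 0.948). The endoplasmic reticulum, hypoxia and immune lists passed with fry (adjusted p of 0.0419, 0.0419 and 0.0329), and the ribosomal and SUMO lists passed camera without treated replicate 1 (0.00241 and 0.0492). Immune markers had 2 higher and 0 lower of 3 (2 adjusted over the list alone).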

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

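Fits on the deposited transformed values, with counts thinned to the smallest library and with the length and GC trend removed were chosen after seeing the data. Every alternative kept the direction of the calls it shared with the reported fit, and of 104 named genes reported past the threshold 85 stayed past it in all 15 alternatives that gave them a value, with 0 turning sign. RLE size factors gave 4424 changed genes, library size only 4205, no filter 4445, a mean of at least 5 CPM 3842, DESeq2 3587, limma-voom 4604, transformed values 4341 and thinned counts 4095. With limma on log2(TPM + 1) 1695 genes changed (759 higher, 936 lower), and on log2(TPM + 0.1) 1712 did (761 and 951); the cause was not tested. The count changed at least 2-fold was 348 (166 higher, 182 lower) with a mean of at least 5 CPM, where fewer genes were tested, 320 (140 and 180) and 517 (221 higher) on the TPM scales, and 145 (75 and 70) on the transformed values; the cause was not tested for the last 3. Leaving out a library, which leaves a lone library assumed to vary like the other group, gave 1866 to 6077 changed genes (949 to 2931 higher, 917 to 3146 lower), fewest without untreated replicate 1. Of the 104 named calls, 15 were lost with log2(TPM + 0.1), 14 with log2(TPM + 1), 11 without untreated replicate 1, 7 without untreated replicate 2, 3 without treated replicate 2, 2 with library size only, 2 with DESeq2, 1 with thinned counts and 0 in each of the other 7 alternatives. Shared replicate numbers are not stated to pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.16 over 12906 genes and 0.4 over 10502 genes with at least 5 CPM, and with the replicate number as a block 6239 genes changed and 14 lists passed, the iron uptake and storage list added (adjusted p = 0.0101). Of genes not past the threshold, SAE1 changed sign with no filter and with a mean of at least 5 CPM (0.00 in both). SUMO3 did so on the TPM scales (-0.04 on both) and MT1X with thinned counts (0.07). Over the fits that left out a library, the values of genes that changed sign ran from -0.01 to 0.01 for SAE1, -0.03 to 0.06 for SUMO3, -0.19 to 0.70 for PIWIL1, -0.64 to 0.05 for STAG3, -0.13 to 0.05 for SLC30A1 and -0.14 to 0.06 for MT1X. Camera called 13 lists with RLE factors, 13 with a mean of at least 5 CPM, 14 with thinned counts (the SUMO list added, adjusted p = 0.0496), 14 with the trend removed (the ribosomal list added, 0.0177) and 14 to 16 without a library. It called 0 with an estimated correlation, where the 2 residual degrees of freedom limit the test. Fry called 13, leaving out 4 of camera's lists and adding 4 others. Of 19381 genes, 6475 were not tested, 2510 of them at 0 counts in every library. How far depth limits the calls was examined only by thinning, which left 12509 genes to test. Thinning used the total counts, which may overstate depth in untreated replicate 1 and treated replicate 2.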

Other observations

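Gene lists beyond the fixed ones were chosen after the data had been seen and were adjusted over 10 lists; the adjusted p with an estimated correlation ran from 0.141 to 0.371 for them as chosen, so none passed that test. Each was also tested without members of the fixed lists and without the 10 largest rises and 10 largest falls, all seen beforehand, and the adjusted p with an estimated correlation then ran from 0.141 to 0.691. Fatty acid synthesis genes fell alongside cholesterol synthesis, 0 higher and 7 lower of 10, with a median of -0.75 (camera adjusted p = 1.46e-05). Without SCD and SREBF1, 5 of 8 fell with a median of -0.48 (camera adjusted p = 0.00187). FADS2, a fatty acid desaturase, fell by 1.60 ± 0.14 (SE) and FASN by 0.87 ± 0.13. Targets of the sterol sensor LXR fell in 5 of 7 cases with a median of -0.76 (camera adjusted p = 0.000164), and in 4 of 6 without SREBF1, with a median of -0.67 (camera adjusted p = 0.00218). The cholesterol exporter gene ABCA1 went from 86.6 ± 0.407 to 29.9 ± 1.85 CPM (SD, n = 2 per group). Aminoacyl-tRNA synthetase genes, several of them ATF4 targets, were higher in 1 and lower in 13 of 20 cases with a median of -0.52 (camera adjusted p = 5.64e-05). Without AARS1 and WARS1, members of the fixed ATF4 list, 1 was higher and 11 lower of 18 with a median of -0.41 (camera adjusted p = 0.00106), among them GARS1 (-0.67).

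Homologous recombination and Fanconi anaemia genes rose in 13 of 15 cases with a median of 0.82 (camera adjusted p = 1.29e-08). EXO1 rose by 1.56 and XRCC2 by 1.21, and FANCD2 was at 0.10 without passing. EGF receptor ligand genes rose in 4 of 6 cases with a median of 1.22 (camera adjusted p = 0.00166), and in 3 of 5 without EREG, with a median of 1.08 (camera adjusted p = 0.00298). HBEGF went from 19.4 ± 0.346 to 59.5 ± 4.91 CPM. HSP70 and cochaperone genes outside the fixed list rose in 6 of 10 cases with a median of 0.43, also with HSPA6 at its bound (camera adjusted p = 0.000194). Without HSPA6, 5 of 9 rose with a median of 0.40 (camera adjusted p = 0.00218). BMP targets were higher in 3 and lower in 1 of 10 cases with a median of 0.31 (camera adjusted p = 0.029), but without ID2 and SMAD7 1 of 8 was higher and 1 lower with a median of 0.22, and the list did not pass (camera adjusted p = 0.39). The median of DNA replication genes exceeded that of mitosis genes by 0.52 (p = 0.00019, two-sided permutation over genes with 100000 resamples, chosen after seeing the data; genes are not independent). Tests of the cholesterol list, set before their results were seen and given here as values only because the near-silent genes were chosen for weighing afterwards, gave a median of -0.57 after removal of the length and GC trend (camera adjusted p = 1.96e-08) and -0.54 after thinning (5.72e-08), with the 8 fatty acid genes above as the third.

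In the patterns that follow, both tests of the near-silent genes and the split of histone genes by level were chosen only after the result was seen; the bounds of the other tests were set before their results, but after the list medians were known. For the rise of DNA replication genes, the median was 0.83 after removal of a trend on transcript length and GC content (camera adjusted p = 3.47e-17), against 0.89 before. That trend held 2.96% of the variance of log2 fold changes, and these values argue against it as the whole cause. After thinning the median was 0.89 (camera adjusted p = 8.16e-17). Random thinning leaves the mean fold of well-counted genes as it was, so this value says little about depth. A larger share of cells in S phase may account for it: replication-dependent histone genes, 10 higher and 2 lower of 31, had a median of 0.91 (camera adjusted p = 0.00325), which met the bound of 0.2 set for that explanation. The 7 histone genes with a mean of at least 5 CPM had a median of 0.12, and the 24 below that level one of 1.09, so this explanation was left open rather than accepted. Levels were low, for instance 0.899 CPM for H4C3 and 0.532 CPM for H1-4 in untreated cells, against 440.3 CPM for RRM2. The histone list can therefore say little about S phase.

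For the rise of NF-kappa-B and inflammation genes, the median was 1.76 after removal of the length and GC trend (camera adjusted p = 4.55e-15), against 1.90 before. Leukocytes in the treated cultures would bring PTPRC. Without TMM factors, PTPRC reached at most 0.511 CPM in treated and 0.241 CPM in untreated libraries. Both lie below the bound of 1 CPM, although LCP1 and CD68 rose. Higher NF-kappa-B output may account for the rise, but 10 further feedback genes had a median of 0.10 (camera adjusted p = 0.195), with TRAF1 (1.47) and NFKBIE (1.34) higher and BCL3 lower (-0.79). Fry, which does not compare the list with other genes, called it upward (fry adjusted p = 0.00699). The median lies between the bounds set for and against it, so the explanation stays open.

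Reads over near-silent genes rose from 56.6 and 57.6 CPM to 172 and 157 CPM, scaled to total counts without TMM factors. After thinning to the smallest total, 14286 and 14583 genes had a read in untreated and 15816 and 15267 in treated libraries. The gap between the nearest libraries was 684. Without thinning, which suits totals that overstate depth, the numbers were 14482 and 14659 against 15816 and 15603. Both comparisons argue against depth. Genomic DNA carried into the treated libraries could give an even gain per kilobase. The gain of 403 olfactory receptor genes was 0.45 times that of other near-silent genes (95% interval 0.35 to 0.55, Poisson counting error only), across the bound of 0.5. That interval is too narrow if reads were counted more than once. Per megabase of transcript the gain was 6.82, 8.77, 8.63 and 7.64 CPM in 4 equal groups of rising transcript length. Genomic DNA and broad low-level transcription cannot be told apart here, because the interval spans the bound and olfactory receptor genes also had fewer reads per kilobase before treatment.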
